A study of Caenorhabditis elegans with 2 samples.

How the data were processed

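Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in 2 biological replicates of whole L1 larvae (6 hours, starved after bleaching) carrying tagged CEH-8. Per the labels, chromatin was sonicated and fragments were 200 to 800 bp. Both samples form 1 group and the replicate numbers are those of the labels.

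Per the file headers, the authors made a peak list for each replicate from its alignment and a control alignment, a list from both replicates together, and a list of optimal IDR peaks derived from the other 3. IDR, the irreproducible discovery rate, is a measure of how alike peaks rank. Being in this list does not by itself mean that a peak was found in both replicates. Of its peaks, 116 had no replicate 2 peak within 200 bp at any rank. The authors' signal value of each peak was used as deposited, to rank and filter peaks within a list. Its scale is not given in the sources used here. The deposited −log10 q-values (−log10 of the caller's q) were read, but no result rests on them. Their Spearman's rho with signal was 0.99996 in replicate 1, 0.491 in replicate 2 and 0.155 in the pooled list. The peak caller, the aligner and the IDR threshold are not given in the sources used here. Every IDR peak was a row of the pooled list, and the IDR list was exactly the 1891 strongest pooled peaks by signal. The other 3 lists held 30000 peaks each, so their lowest signals were not set by a common threshold. Read depth per sample is unknown, and no interval that would need it is given. The intervals of shares are exact binomial intervals over peaks, that of a correlation is from a bootstrap over peaks and that of a logistic odds ratio is a Wald interval. All treat peaks as independent and cover counting error only.

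The files name the assembly ce11. Peaks were set beside Ensembl release 115 gene models and the reference sequence of WBcel235, the same assembly. No peak ran past the end of a chromosome, and 99.9% of annotated start codons read ATG in the sequence. There were 19973 protein-coding genes on the 6 nuclear chromosomes. A gene start was its outermost annotated start. Where a summit fell in several genomic classes, the order was promoter, 5' UTR, coding exon, intron, 3' UTR, non-coding RNA gene, other intergenic. Of the names in the gene lists, ceh-35, ceh-44, bus-8, lin-4, mir-71 and tts-1 did not match a protein-coding gene. Some names stand for several genes, so that the 50 histone names gave 72 genes, the 20 heat shock names 22 and the 1354 chemoreceptor names 1365.

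Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 was used. Replicates were compared by overlap of their 1891 strongest peaks (at least 50% of each peak) with 1000 shuffles within chromosomes, whose smallest p is 0.001 one-sided and 0.002 two-sided. A peak found in both replicates is an IDR peak with a summit within 200 bp of one of the 1891 strongest peaks of each. Genomic classes were tested with the same number of shuffles, chromosomes with exact binomial tests against length, and gene lists with Fisher's exact two-sided test, each with Benjamini-Hochberg adjustment over the classes, the chromosomes or the 20 lists. Motifs on either strand within 50 bp of the summit were compared with windows of the same total length centred 250 bp to each side, by an exact binomial test on peaks with the motif in only one of the 2, adjusted over 10 motifs. GC-matched windows were within 1 percentage point of GC and found for 1814 peaks. The threshold was 0.05.

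The genes named follow a rule fixed before the data were examined: those nearest to the 15 strongest IDR peaks within 1000 bp, ceh-8 and unc-119, all RIA genes, and up to 4 genes with the strongest peaks in every other list. The tests, gene lists and most alternatives were fixed at that time too. Chosen after seeing the data were the restriction to peaks found in both replicates, leaving out X or the peaks within 20000 bp of ceh-8, GC-matched windows for motifs other than TAATTA, and the split of the 50 strongest peaks by chromosome.

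The steps were tested on simulated data with known answers. With 40% of 1891 peaks placed near gene starts, 60.6% were counted there where 60.8% was planted. Replicate overlap was 60.1% where 60% was planted. A gene list with peaks at 30% of its members was called in 100 of 100 draws, and one at the background rate in 6. TAATTA written at summits gave 23.8% where 23.6% was planted. A search of 8-base words recovered the 1 word written at 5% of summits and called 0 words where none was written. The simulated summits were random positions. The search was therefore not tested where summits and flanks differ in base composition.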

Results

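CEH-8 is a paired-like homeodomain protein of the nematode *Caenorhabditis elegans*, and its gene is a known marker of the RIA interneurons. Sites occupied by a GFP-tagged copy were mapped by chromatin immunoprecipitation with an anti-GFP antibody in whole L1 larvae of 6 hours that had been starved after bleaching. The transgene carried ceh-8 with its tag together with unc-119(+), a rescue marker for the unc-119 mutation of the strain. There were 2 biological replicates of this 1 group, so no comparison between conditions could be made. The deposited lists held 30000 peaks for each replicate, 30000 for the pooled reads and 1891 optimal IDR peaks. The authors derived the IDR list from the other 3, and it held the 1891 strongest pooled peaks, of which 116 had no replicate 2 peak within 200 bp at any rank and 11 no replicate 1 peak. Each peak's signal is the authors' value and ranks peaks within a list. Read depth is unknown from these files. All coordinates are on ce11.

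The strongest IDR peak lay in the promoter of rpl-3, which encodes a protein of the large ribosomal subunit (III, 3867445 to 3867694, 281 bp from the gene start). It ranked 4 in replicate 1 and 1 in replicate 2. The promoter of rpl-35 held the peak of rank 7, and that of mrck-1, a kinase gene, the peak of rank 8. Of the 15 strongest peaks 8 lay on the X chromosome, among them the promoter peak of nspc-17 at rank 4 (X, 14525722 to 14526106). The peaks of ranks 6 and 15 lay in the promoters of Y17G9B.5 and Y22D7AL.10. That of rank 10 was nearest to the start of ZK1248.17, at 728 bp. It lay past the far end of ZK1248.17, in the promoter of another gene. The peak of rank 2 (II, 2973950 to 2974352) was intergenic, 2486 bp from the nearest start, that of nhr-88. Singled out after its values were seen, it ranked 1 in replicate 1 and 117 in replicate 2, and 71.3% of the bases within 50 bp of its summit were G or C.

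Which sites the replicates shared was asked first. Of the 1891 strongest peaks of replicate 1, 1014 overlapped one of the 1891 strongest of replicate 2 by at least 50% of each peak. This was 53.6% (exact 95% interval 51.3% to 55.9%), against a mean of 0.598% when the peaks of replicate 2 were shuffled within chromosomes (one-sided p = 0.001, the smallest that 1000 shuffles can give). Over 1093 shared pairs of strong peaks, Spearman's rho of signal was 0.659, across peaks that are not independent replicates and were chosen as strong in both. At the 1764 IDR peaks with a peak in both lists rho was 0.430. Summits at these 1764 lay a median of 23 bp apart. The sharing was unequal: all 100 of the strongest peaks of replicate 2 had a summit within 200 bp of one of the 1891 strongest of replicate 1, but 75 of the strongest 100 of replicate 1 had one in replicate 2. Among the IDR peaks, 1085 had such a strong peak in both replicates, 408 in replicate 1 only, 351 in replicate 2 only and 47 in neither. The 408 had a median GC content of 56.4%, against 45.5% for the 1085 found in both.

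**Figure D1:**
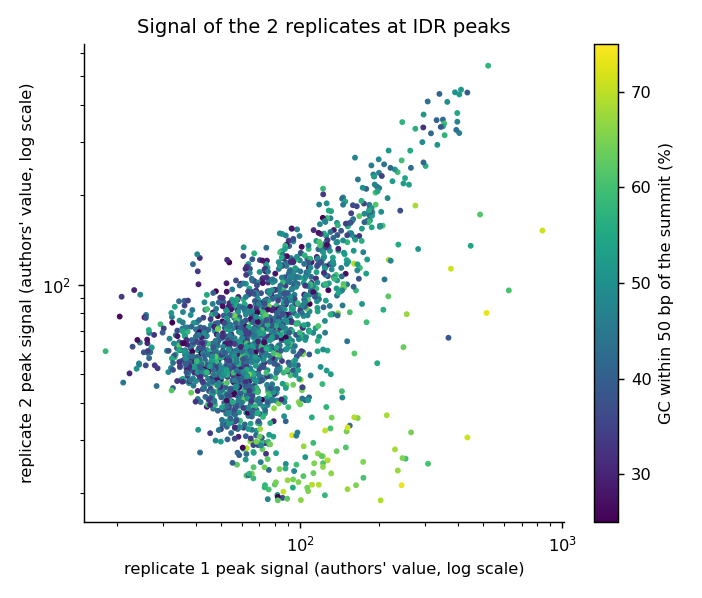
Signal of the replicate 1 peak (x axis) and the replicate 2 peak (y axis) nearest to each IDR summit, both the authors' values on log axes, for the 1764 IDR peaks with a peak within 200 bp in both lists. Color gives the GC content within 50 bp of the IDR summit; GC-rich peaks tend toward high replicate 1 and low replicate 2 signal, while the strongest peak, at rpl-3, has 522 and 543.

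The peaks gathered upstream of genes. Promoters, taken as the 1000 bp upstream of a protein-coding gene start, held 841 of the 1891 summits, or 44.5% against 18% of shuffled peaks (2.47-fold). Genes for non-coding RNA outside the protein-coding classes held 42 summits, 3.23-fold the shuffled number. Coding exons held 5.98% against 21.4%, introns 20.9% against 31.4%, and 3' UTRs 0.476% against 2.44%. These 5 classes differed from the shuffles (two-sided permutation test by shuffling, Benjamini-Hochberg adjusted p = 0.0028 each), while 5' UTRs (adjusted p = 0.62) and other intergenic sequence (adjusted p = 0.77) were not told apart from them. Counting both sides of a start, 987 summits (52.2%, exact 95% interval 49.9% to 54.5%) lay within 1000 bp of one, against 34.3% of shuffled peaks (one-sided p = 0.001, the smallest possible). Strong peaks were nearer to starts: 61.2% of the 472 strongest lay within 1000 bp, against 47.9% of the 472 weakest (Fisher's exact two-sided p = 4.94e-05). Within the stronger 50% of IDR peaks the difference was in the same direction but did not pass with fewer peaks, 61.9% against 52.5% of 236 each (exact p = 0.051). Coding exons held 0.829% of the 1085 peaks found in both replicates, 3.49% of the strongest peaks of replicate 2 alone and 9.84% of those of replicate 1 alone, and 3' UTRs held 0.952% with replicate 2 alone. In the stronger 50% of IDR peaks the fold for non-coding RNA genes was 1.96 (permutation adjusted p = 0.045).

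**Figure D2:**
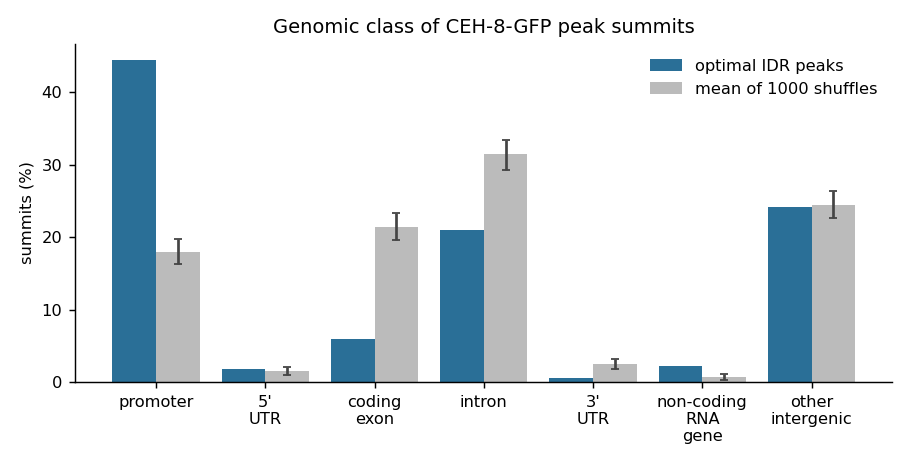
Share of the 1891 IDR summits in each genomic class (blue, y axis in percent) beside the mean of 1000 shuffles within chromosomes (grey, with bars that span 95% of the shuffles). Promoters hold 44.5% of summits against 18% in the shuffles.

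By chromosome, X carried more peaks than its length would give, 416 or 22% on 17.7% of the sequence (exact binomial test, adjusted p = 9.53e-06). Chromosome III was also above its share (15.9% against 13.7%, exact adjusted p = 0.012). Among the 1085 peaks found in both replicates its share was much the same, 15.7%, but with fewer peaks did not pass (exact adjusted p = 0.098). Chromosomes IV (14% against 17.4%) and V (16.6% against 20.9%) were below it, with adjusted p of 9.63e-05 and 1.01e-05, and I and II were not told apart from it. Chromosome I passed the test above its share in the strongest peaks of replicate 1 alone (exact adjusted p = 0.0034). Peaks on X lay near gene starts less often: 162 of 416 (38.9%) were within 1000 bp of one, against 825 of 1475 on the autosomes (55.9%, Fisher's exact two-sided p = 1.17e-09). Shuffled peaks did too, with 28.9% on X and 35.8% on the autosomes, so that the folds over the shuffles were 1.35 and 1.56, a difference that was not tested. Of the 50 strongest peaks 15 were on X (30%, exact p = 0.039), but the shares of the 100 strongest (23%, exact p = 0.19) and 200 strongest (20%, exact p = 0.40) were not told apart from that of its length. Of the 15, 3 were within 1000 bp of a start, against 25 of the 35 on autosomes (Fisher's exact p = 0.0014, a split chosen after the peaks were seen).

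Which groups of genes carried peaks was asked with 20 gene lists. Each summit within 1000 bp of a start was given to the nearest protein-coding gene, which gave 963 genes, 4.82% of 19973. The lists of RIA interneuron genes, cytoplasmic ribosomal proteins and cuticle collagens carried peaks more often than other genes, and chemoreceptors less often.

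Ribosomal protein genes stood out by number. Of 81, 21 had a peak (25.9% against 4.74% of other genes, odds ratio 7.04, Fisher's exact test, Benjamini-Hochberg adjusted p = 3.11e-09 over the lists). Of those 21 peaks 17 were found in both replicates, and the odds ratio was 13.7 when a summit was given to every start within 1000 bp. Besides rpl-3 and rpl-35 they included rpl-12 (IV, 13240592 to 13240780, 14 bp from the start, signal 583, rank 30) and rpl-15 (rank 34), all in promoters. None of the 21 had TAATTA, the site typical of paired-like homeodomains, within 50 bp of its summit. Among all IDR peaks 7.19% had one, so 21 peaks are too few to tell a difference.

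Of the 7 RIA interneuron genes 4 had a peak (57.1% against 4.80%, odds ratio 26.4, Fisher's exact adjusted p = 8.36e-04). The peak at ceh-8 itself ranked 23. The others were at glr-3, glr-6 and ttx-7. The glutamate receptor gene glr-3 had a promoter peak 125 bp from its start (I, 7117508 to 7117857, rank 573). At glr-6, of the same family, the summit lay 55 bp inside the gene, in sequence that is the promoter of another gene (rank 1731). The gene ttx-7, which encodes an inositol monophosphatase, had a promoter peak (rank 1764). The peaks at ceh-8 and glr-3 were found in both replicates, those at glr-6 and ttx-7 were not. The genes eat-4, gar-3 and unc-42 had no IDR peak near their start. Without the peaks around ceh-8, which is on the transgene, 3 of 7 remained (odds ratio 14.9, exact adjusted p = 0.017), and with the strongest peaks of replicate 1 alone the odds ratio was 15.2 (adjusted p = 0.016). The call was lost with the strongest peaks of replicate 2 alone (2 of 7, odds ratio 8.33, exact adjusted p = 0.18), in the stronger 50% of IDR peaks (adjusted p = 0.091) and among peaks found in both replicates (adjusted p = 0.11).

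Cuticle collagen genes had a peak in 21 of 156 cases (13.5% against 4.75%, odds ratio 3.12, Fisher's exact adjusted p = 1.33e-04), but 2 of the 21 were found in both replicates. One of those 2 was at col-63, in or beside ceh-8, which is on the transgene. Without the peaks around ceh-8, 20 of 156 had a peak (odds ratio 2.95, exact adjusted p = 4.04e-04). The 4 strongest collagen peaks, at col-105, col-176, col-98 and col-107, lay in coding exons with a GC content of 64.4% to 73.3%. The peak at col-105 (IV, 1358184 to 1358391) ranked 58 in replicate 1 and 22553 in replicate 2, and that at col-107 ranked 114 in replicate 1 with none in replicate 2. With the strongest peaks of replicate 2 alone, 2 of 156 had one and the odds ratio was 0.268 (exact adjusted p = 0.18). It was 7.48 with those of replicate 1 alone (exact adjusted p = 1.57e-18). Within 500 bp of the start it was 0.337 (exact adjusted p = 0.33). The collagen gene sqt-3, in the epidermis list, likewise had a coding-exon peak in replicate 1 and none in replicate 2.

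Chemoreceptor genes carried peaks less often, 35 of 1365 (2.56% against 4.99%, odds ratio 0.501, Fisher's exact adjusted p = 1.33e-04). The strongest peaks were at srh-16 (rank 204), str-96, str-84 and sri-5. Peaks shuffled within chromosomes placed a mean of 39.8 such genes near a peak, and 35 was not told apart from that (permutation test, adjusted p = 0.96). This compares with random positions, whereas Fisher's test compares with other genes. Chemoreceptor genes thus had fewer peaks than other genes, but not detectably fewer than random placement gave.

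The other 16 lists did not pass the test. Pan-neuronal genes had 5 of 32 (odds ratio 3.67, exact adjusted p = 0.070), the strongest at unc-104, a kinesin gene (intron, rank 436). They passed within 2000 bp (odds ratio 6.99, exact adjusted p = 6.90e-05) and with every annotated transcript start (7.05, adjusted p = 1.47e-04). In the stronger 50% of IDR peaks 1 of 32 had a peak (odds ratio 1.18, exact adjusted p = 1), as among peaks found in both replicates (1.04, adjusted p = 0.97). Glutamate receptors had 3 of 19 (exact adjusted p = 0.20), glr-2 beside the 2 RIA genes. Heat shock proteins had 3 of 22, led by hsp-1 (rank 87) and hsp-3 (rank 225), with exact adjusted p = 0.25, and passed when a summit was given to every start within 1000 bp (odds ratio 5.38, 0.0093). Without peaks over non-coding RNA genes 1 of 22 had a peak (odds ratio 1.12, exact adjusted p = 0.91). Insulin-like peptides had 4 of 39 (exact adjusted p = 0.29), led by ins-39 (rank 52) and ins-1 (rank 144), and passed within 2000 bp (0.030). Homeobox genes had 5 of 95 (exact adjusted p = 1), among them ttx-3 (rank 693), ceh-38 (rank 557) and ceh-23 (rank 1086). Nuclear hormone receptors had 8 of 269 (exact adjusted p = 0.39), the strongest at nhr-47 (rank 327). Neuropeptides had 3 of 102 (exact adjusted p = 0.75), nlp-69, nlp-1 and flp-5. Of the L1 starvation list, aak-2, akt-1 and hlh-30 had a peak (3 of 29, exact adjusted p = 0.36), and of the histones his-37, his-24 and his-68 (3 of 72, adjusted p = 1). Body wall muscle (act-4), epidermis (sqt-3) and pharynx (abu-11) had 1 gene each (exact adjusted p = 1 each). The lists of neurotransmitter identity, intestine, glia and germline had 0 (of 19, 30, 19 and 30), with exact adjusted p of 1, 0.67, 1 and 0.67.

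**Figure D3:**
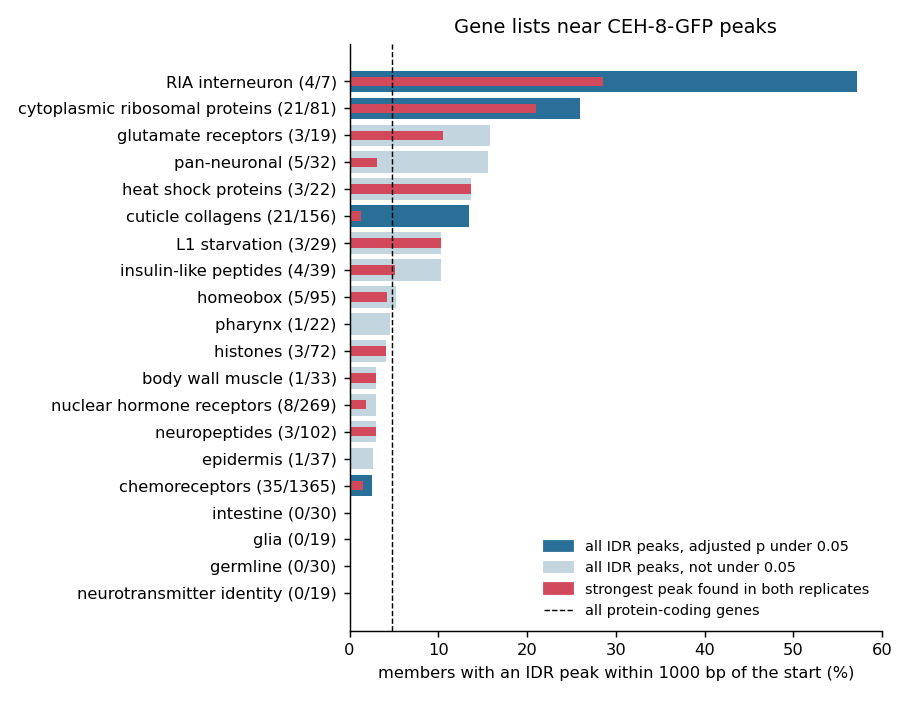
Percent of each list's members with an IDR peak within 1000 bp of their start (x axis; members with a peak and members matched in parentheses). Dark blue marks lists with an adjusted p under 0.05, red the members whose strongest peak was found in both replicates, and the dashed line all protein-coding genes (4.82%); the ribosomal list keeps 17 of its 21 and the collagen list 2 of 21.

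The transgene's own loci were looked at as a check on the labels. At ceh-8 (WBGene00000433, I, 8245505 to 8250948, minus strand) the strongest IDR peak lay in an intron, 168 bp inside the gene start (8250672 to 8250864, signal 638, rank 23, and ranks 36 and 18 in replicates 1 and 2). A second strong peak lay further inside the gene (8247608 to 8247738, signal 372, rank 69). Within 5000 bp of the gene there were 7 IDR summits, a number reached by 0.0531% of windows of that length on chromosome I, whose median was 0. No window held more than 7. The windows counted include those over ceh-8 itself, so the 0.0531% is not a share of other places. At unc-119 (III, 10902641 to 10908935) there was 1 IDR peak, in an intron (10905097 to 10905446, signal 130, rank 910), and 28.6% of windows of that length on chromosome III held as many.

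**Figure D4:**
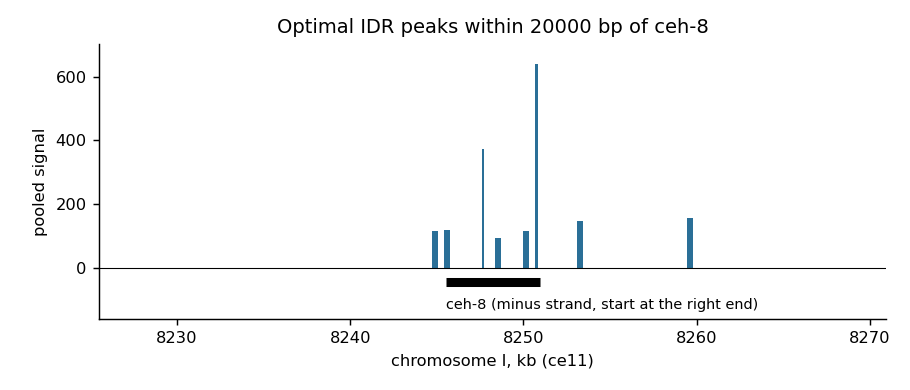
IDR peaks within 20000 bp of ceh-8, with position on chromosome I in kb (x axis) and the authors' pooled signal (y axis); each bar spans its peak and the black line is the gene. The peak near the gene start has a signal of 638 and the one within the gene 372.

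Sequence under the summits was compared with flanks of the same peaks, since paired-like homeodomains bind TAAT cores. TAATTA lay within 50 bp of 136 summits and in the flanks of 116 peaks, a difference that did not pass the test (ratio 1.17, exact binomial test on discordant peaks, p = 0.22). The palindrome TAATNNNATTA, which paired-class homeodomain dimers can bind, lay at 36 summits against 8 flanks (ratio 4.50, exact adjusted p = 5.09e-05). TAATTG lay at 230 against 159 (ratio 1.45, exact adjusted p = 2.07e-04) and GAGAGA at 418 against 156 (ratio 2.68, adjusted p = 1.39e-31). CCGCCC (116 against 44, exact adjusted p = 6.60e-09) and TTGCGCAA (15 against 4, adjusted p = 0.027) were also more frequent at summits. WGATAR, the GATA factor site, was less frequent (279 against 411, exact adjusted p = 3.92e-08), as was TTTTTTT (159 against 416, adjusted p = 4.12e-31). CAGCTG (ratio 1.43, exact adjusted p = 0.054) and TGACTCA (1.60, adjusted p = 0.13) did not pass, but both did in the strongest peaks of replicate 1 alone (1.90 and 2.58, adjusted p = 2.51e-04 and 0.0048). In the stronger 50% of IDR peaks the calls for TAATTG (ratio 1.23, exact adjusted p = 0.18) and TTGCGCAA (4.50, adjusted p = 0.11) were lost, the latter also among peaks found in both replicates, where its ratio of 3.67 rested on fewer peaks (11 against 3, adjusted p = 0.072).

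The background mattered for several of these. Against windows of the same GC content at the same distance from other gene starts, TAATTA was 3.32 times as frequent at summits (136 against 41 of 1814 peaks, exact p = 1.02e-13), TAATTG was 2.64 times and TAATNNNATTA 18 times as frequent, whereas the calls for CCGCCC (ratio 0.971), WGATAR (0.959) and TTTTTTT (0.811) were lost. With the strongest peaks of replicate 2 alone the TAATTA ratio to flanks was 1.40 (exact p = 0.0042). At the IDR peaks TAATTA also passed within 100 bp of the summit (245 against 199, ratio 1.23, exact p = 0.020), whereas the number of TAAT cores was lower at summits than in flanks (ratio 0.888, p = 1.27e-11). TAATTA was as frequent in the 472 strongest as in the 472 weakest peaks, 29 in each (Fisher's exact p = 1).

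**Figure D5:**
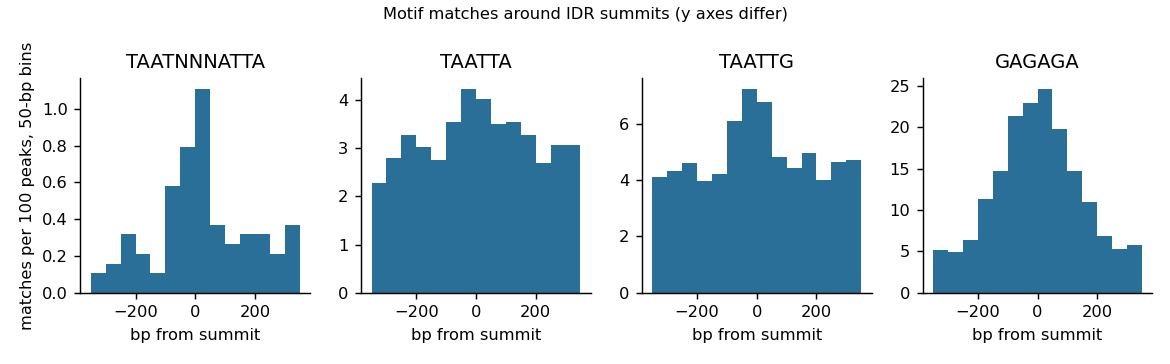
Matches per 100 IDR peaks in bins of 50 bp (y axis; scales differ) by distance of the match from the summit in bp (x axis), for 4 motifs. TAATNNNATTA, TAATTG and GAGAGA rise toward the summit. TAATTA is also highest in the bins beside the summit (4.23 and 4.02), but at 136 summits against 116 flanks did not pass the test.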

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

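Chosen only after the result was seen were the tests of GC content and of coding exons at strong replicate 1 peaks, the counts at the other X peaks, the share of the 15 strong X peaks with TAATTA, and the requirement on the interval in the model with GC.

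Strong peaks on X lay near gene starts less often than strong autosomal peaks. Of the 15 X peaks of the top 50, 20% were within 1000 bp of a start, against 71.4% of the 35 autosomal ones. Of X peaks shuffled within X 28.9% were, a difference from the 15 that was not tested. The 12-base motif TCGCGCAGGGAG, known from the sites that recruit the dosage compensation complex to X, lay with up to 2 mismatches within 150 bp of 11 of the 15 X peaks of the top 50, or 73.3% (exact 95% interval 44.9% to 92.2%). It lay at 4 of 160 autosomal peaks of the top 200 (2.50%, Fisher's exact p = 1.98e-11) and at 14 of the other 401 X peaks (3.49%), so the strongest X peaks may mark such recruitment sites. TAATTA lay at 1 of the 15, 6.67% (exact 95% interval 0.169% to 31.9%), so most of them had none. As 7.19% of all IDR summits had one, this was no trait of the X peaks. Whether TAATTA is more common at X peaks of the top 200 than at other IDR peaks could not be told. With 4 of 40 (odds ratio 1.45, Fisher's exact p = 0.53) these were too few. Whether CEH-8 binds at the strong X peaks by other means was not tested, and a library without the tag was not analysed here.

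Peaks at ribosomal protein genes and over non-coding RNA genes, 356 together, had TAATTA at 9 summits. This was 2.53% against 8.27% of the other IDR peaks (odds ratio 0.288, Fisher's exact p = 5.29e-05). Most of the 356 thus had none, as did most other IDR peaks. The contrast was not adjusted for GC content, so it cannot decide on TAATTA sites as their source. The median GC content of the 356 was 51.5% against 44.6%. In a logistic model with GC as a covariate the odds ratio was 0.728 (95% interval 0.352 to 1.51, Wald p = 0.39 across peaks, not exact), so GC content could account for the lack of TAATTA, though the interval leaves room for a real deficit. Why the peaks are there stays open, and no other biological explanation was tested.

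Of the 1000 strongest replicate 1 peaks, 303 had no counterpart among the 1891 strongest of replicate 2. They had a median GC content of 63.4% against 46.5% for the 697 shared ones (permutation p = 1e-05, the smallest 100000 resamples can give), and 32% lay in coding exons against 0.574%. A second genomic copy of at least 50% of their 31-base words was found for 3.30% of them (exact 95% interval 1.59% to 5.99%). It was found for 1.43% of the shared peaks (odds ratio 2.34, Fisher's exact p = 0.081). Only exact copies were counted, so diverged repeats were not looked for. The low share stands against exact repeats as the source of most of these 303 peaks. TAATTA lay at 0.330% of them, against 7.19% of the IDR peaks (Fisher's exact p = 2.71e-08). As this was not adjusted for GC, the difference cannot decide on TAATTA sites as their source. Over 1093 shared peaks the ratio of replicate 1 to replicate 2 signal rose with GC (Spearman's rho 0.223, bootstrap 95% interval 0.167 to 0.279). This is the direction that better recovery of GC-rich fragments in replicate 1 would give. The median log2 ratio was 0.16 in the most GC-rich 25% and -0.08 in the least. As these peaks were chosen as strong in both replicates, the largest ratios were left out, and the values cannot give the size of such an effect. Whether such recovery could account for peaks that are missing in replicate 2 stays open, as does a biological difference between the larvae of the 2 replicates, which was not tested.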

How the results depend on the processing

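The restriction to peaks found in both replicates, leaving out X or the peaks around ceh-8, and GC-matched windows for motifs other than TAATTA were chosen after seeing the data. Replicate overlap (36.1% to 59.1% over 6 alternatives, the lowest with all peaks of each replicate, against 9.95% in the shuffles), peaks near gene starts (39.1% to 68.5% over 11), the 5 genomic classes called and the share of peaks on X (20.3% to 22.6% over 5) kept their call and direction, as did ribosomal proteins (5.42 to 13.7 over 14), TAATNNNATTA and GAGAGA (6 alternatives each). The strongest 1891 pooled peaks are the IDR list itself, so that alternative tested nothing. Spearman's rho of signal was 0.444 over all overlapping peaks and 0.430 at IDR peaks, the first over a wider range of weak peaks. The number of lists called was 2 in the stronger 50% of IDR peaks and 2 among peaks found in both replicates, and 2 to 4 leaving out a replicate in turn. For TAATTA the ratio was 1.12 to 1.40 leaving out a replicate (passing in replicate 2 alone), 1.23 within 100 bp and 3.32 against GC-matched windows, where it passed, and 0.888 for the number of TAAT cores, which passed the other way. RIA genes were at 8.33 to 15.2 leaving out a replicate, 14.6 in the stronger 50% and 12.9 among peaks found in both replicates, with fewer peaks in each, and chemoreceptors at 0.880 of their shuffled number. Pan-neuronal genes passed at 6.99 within 2000 bp and 7.05 with every transcript start, insulin-like peptides at 3.35 within 2000 bp and heat shock proteins at 5.38 with every start within 1000 bp. Collagens went from 0.268 to 7.48 leaving out a replicate, and were 2.25 in the stronger 50%, 0.417 among peaks found in both replicates and 0.337 within 500 bp. Of these settings only replicate 1 alone kept the call for collagens. Leaving out a replicate, neuropeptides ran from 0.610 to 1.07, histones from 0.877 to 1.22 and epidermis from 0 to 1.78. These and the following changes of direction were of results called under neither setting, except CCGCCC, which lost its call at 0.971 against GC-matched windows, where CAGCTG was 0.823. In the stronger 50% of peaks 5' UTRs were at 0.899, neuropeptides 1.11, epidermis 1.01 and histones 1.04. Among peaks found in both replicates 5' UTRs were at 0.836, body wall muscle 1.01 and histones 1.40. Within 500 bp insulin-like peptides were at 0.686, histones 1.14 and the L1 starvation list 0.932. Pharynx was at 1.20 on autosomes, 1.12 without peaks over non-coding RNA genes and 1.29 against shuffled peaks, as fold over their mean, where histones were 2.44. Homeobox genes were at 0.870 without the peaks around ceh-8 and 0.794 with every start within 1000 bp, where histones were 1.30; epidermis was 1.02 with every transcript start. The cause of these changes was not tested. With 2 replicates and unknown read depth, weak peaks cannot be told from missing ones.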

Other observations

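The values in this part were all chosen after seeing the data. Summits lay near small non-coding RNA genes far more often than shuffled peaks. Within 200 bp of a tRNA gene there were 59 summits (10.4-fold over the shuffled mean), of a snoRNA gene 49 (14.5-fold) and of a snRNA gene 14 (12-fold), each with an adjusted two-sided permutation p of 0.0028. MicroRNA genes had 9 (3.94-fold, permutation adjusted p = 0.0028) and lincRNA genes 12 (2.01-fold, adjusted p = 0.035). Genes annotated as ncRNA without a further class had 273 (3.99-fold, permutation adjusted p = 0.0028). At rRNA genes there were 0, against a shuffled mean of 0.332.

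Of 11861 8-base words seen in at least 10 windows, 456 were more frequent at summits than in flanks. The leading one was AGACGCAG, at 136 summits against 14 flanks (exact binomial test, adjusted p = 3.31e-22), and at 91 against 7 among peaks found in both replicates. Against GC-matched windows it was 3.02 times as frequent (139 against 46 of 1814 peaks, exact p = 7.21e-13), counted by the midpoint of the match. The other words were compared with flanks not matched for GC content. Some are shifts of one sequence, such as AGACGCAG, GAGACGCA and GACGCAGA, so 456 is not a number of separate sequences.

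The 36 peaks with TAATNNNATTA had a median GC content of 29.7%, and 26 of them were found in both replicates (72.2% against 57.1% of the other IDR peaks, Fisher's exact p = 0.088). The strongest was in the promoter of Y73B6BL.29 (IV, 6321829 to 6321976, rank 57). One lay in an intron of ceh-8 itself (I, 8248370 to 8248719, rank 1662, not in both replicates), and another at the promoter of ceh-23 (rank 1086). A further one, of rank 190, lay past the far end of nlp-69, 904 bp from its start, in an intron of another gene.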
